A study of Mus musculus with 5 samples.

How the data were processed

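RNA expression was measured on 5 one-colour oligonucleotide arrays from cultured cells labelled as mouse aortic endothelial cells (C57BL/6J background). By title, 3 were control and 2 were TNF-LTBR, all with a time of 24 h in the title. Per the labels, total RNA was isolated with a column kit and biotin-labelled by in vitro transcription. Groups and replicate numbers were taken from the sample titles. The treatment text is the same for all 5 samples and names PBS only, so the identity of the TNF-LTBR group rests on its titles. The agonists behind the name TNF-LTBR and their doses are not given in the sources used here. Nothing in the labels says whether the arrays of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

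The deposited values were array intensities on a linear scale, 1 value per probe set and array. The submitters' processing notes name GCOS version 1.4. The algorithm that summarised probes into probe sets and the scaling target are not given in the sources used here. The values themselves show scaling: without the lowest and highest 2% of probe sets, the mean intensity was 500 on each of the 5 arrays. Array medians lay between 109.9 and 120.7, a ratio of 1.10, and the values were therefore used as deposited, under a rule that allowed a difference of up to 10%. The lowest intensity was 0.1 on every array. The number of arrays limits the precision.

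Each array held 45101 probe sets. Gene symbols came from the platform annotation table, in which 34958 probe sets had 1 symbol, 932 had several and 9211 had none listed. Only probe sets with 1 symbol were named. Of these, 34754 were matched by Entrez ID to a RefSeq gene table of the GRCm38.p6 assembly, which changed 0 symbols. No coordinates were used, because no source names the build behind the probe sets. Intensities were transformed as log2(intensity + 16), so fold changes are on that scale, which understates changes of dim genes. Each of 18194 genes was represented by its probe set with the highest mean over all 5 arrays. The 60% of genes with the highest mean were tested, 10916 genes with a mean log2 value of at least 7.17, which corresponds to an intensity of 128.

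TNF-LTBR was compared with control in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The fit had 3 residual degrees of freedom. An exact permutation test of 3 against 2 arrays cannot give a two-sided p under 0.1. Gene lists were tested with limma's camera on the same values at a preset inter-gene correlation of 0.01, with adjustment over the 24 lists that kept at least 5 genes. Camera compares a list with all other genes. The limma p-values of a list's members were also adjusted over that list alone. This was not part of the planned test and does not correct for the number of lists. Camera with an estimated correlation and fry were the alternative list tests. Where a range of a list's adjusted p over the alternatives is given below, it does not include these tests. It covers only the fits at the preset correlation, at most 17 per list. The 26 lists covered NF-kB signalling, chemokines, cytokines, lymphoid tissue organizer genes, the TNF superfamily, adhesion, interferon responses, antigen presentation, complement, apoptosis, coagulation, matrix, oxidative stress, cell cycle, cholesterol synthesis, glycolysis, Notch, angiogenic factors, and markers of endothelial, lymphatic, smooth muscle, fibroblast, macrophage and lymphocyte cells. They held 423 distinct genes, of which 390 had a probe set with a single symbol, 4 of them under a newer symbol. The other 33 were not analysed here. They include Ccl19 and Ccl21a, whose probe sets carry several symbols.

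The test, the lists, the rule for named genes and all alternatives except 2 were fixed before the data were examined. The rule took up to 10 genes past the threshold per direction without overlap between groups, up to 4 members past the threshold from each list or, of a list with none, up to 2 with the smallest p, and, whatever their result, Tnfrsf1a, Ltbr, Nfkbia, Nfkb2, Relb, Birc3, Vcam1, Icam1, Sele, Madcam1, Ccl2, Cxcl1, Cxcl13, Ccl19, Ccl21a, Tnfsf13b and Il7. Other genes named below were chosen after their values were seen, as is said at each. The alternatives were other pseudocounts (1 and 64), no filter and a stricter filter that kept 40% of genes, quantile normalization, median centring, every probe set on its own, no probe sets with shared-sequence suffixes, eBayes without the trend, array quality weights, the replicate number as a block, and leaving out each array. The suffixes taken as shared-sequence were _x_at, _s_at, _a_at and _f_at. Whether each marks sequence shared with other genes was not examined. Irf1 and the brightest probe sets of Birc3 and Nfkb2 end in _a_at and were left out by this setting. Added after seeing the data were the first principal component of the residuals as a covariate, and a block that paired arrays of the 2 groups by their correlation, which is read from the values and not from the labels.

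The procedure was tested on simulated data. With known changes added to the deposited arrays over the 10916 genes, 16% of genes changed by 1 on the log2 scale were recovered, 66% of those changed by 2, 92% of those changed by 3 and 92% of those changed by 4, with 4 unchanged genes called. With simulated arrays that had the measured spread between replicates, the shares were 30%, 90%, 92% and 98%, with 12 unchanged genes called. With the first residual component taken out of that spread they were 76%, 98%, 100% and 98%, with 11 unchanged genes called. Each share was over 50 genes. Genes of all sizes were changed together, which eases the adjustment, so the shares may be too high where few genes differ. The deposited arrays keep any true difference between the groups, so the 4 calls there need not be false. Camera called a list shifted by 1 on the log2 scale in 20 of 20 simulations of independent genes, and called 4 of 440 unshifted lists.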

Results

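The data were expression profiles on 5 whole-transcriptome arrays at 24 h. The cultures were labelled as mouse aortic endothelial cells, the cells that line the vessel wall. By title, 3 arrays were control and 2 were TNF-LTBR. TNF is an inflammatory cytokine that signals through the receptor encoded by Tnfrsf1a, and LTBR is the lymphotoxin beta receptor, encoded by Ltbr. The design text describes stimulation with agonists, and the series title concerns combined signalling of these receptors through NF-kB. The comparison therefore asked which transcripts differed between cultures titled TNF-LTBR and cultures titled control. Median intensity was 110, 113.3 and 115.2 on control arrays 1 to 3, and 120.7 and 109.9 on TNF-LTBR arrays 1 and 2. All values below are log2(intensity + 16), as mean ± SD with n = 3 control and n = 2 TNF-LTBR arrays, and folds are on that scale.

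The list of NF-kB subunits and feedback inhibitors rose in the TNF-LTBR cultures by camera (adjusted p 1.09e-13), and missed the threshold with an estimated correlation (adjusted p = 0.148). The mean of 16 measured members was 9.46 ± 0.06 in control and 10.26 ± 0.03 in TNF-LTBR, with 14 members higher and 2 lower, and the groups overlapped for 7 members. Birc3, which encodes an inhibitor of apoptosis, lay at 9.38 ± 0.28 in control and 10.96 ± 0.02 in TNF-LTBR, 2.99-fold. Nfkb2, the precursor subunit of the non-canonical pathway, lay at 8.41 ± 0.35 and 10.22 ± 0.04, 3.52-fold, and its partner Relb was at 1.55-fold. The dimmer probe sets of Birc3 and Nfkb2 differed by 0.02 and 0.92 on the log2 scale. Nfkbia, which encodes the NF-kB inhibitor IkB-alpha, was at 1.79-fold on its brightest probe set, and its other probe sets differed by 1.04 to 1.62 on the log2 scale.

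The NF-kB list also passed fry, with an adjusted p of 0.0204 for a change in one direction and 0.00102 for changes in either direction. Both TNF-LTBR arrays lay above all controls for 9 of the 16 members, against 10% by chance, and for the list mean. Over all genes tested, 0 members passed (limma, smallest adjusted p 0.999). Adjusted over the list alone, with no correction across lists, 5 members passed in limma, namely Birc3, Nfkb2, Birc2, Nfkbie and Traf2. Their adjusted p over the list alone was 0.00337 for Birc3, Nfkb2 and Nfkbie, 0.00364 for Birc2 and 0.0313 for Traf2. Nfkbie, another NF-kB inhibitor, was at 7.27-fold and Traf2, an adaptor of TNF receptors, at 1.76-fold. Nfkbie and Traf2 were chosen after their values were seen, and the Nfkbie probe set carries the suffix for sequence shared with other transcripts. Its other probe set differed by 2.11 on the log2 scale.

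**Figure D1:**
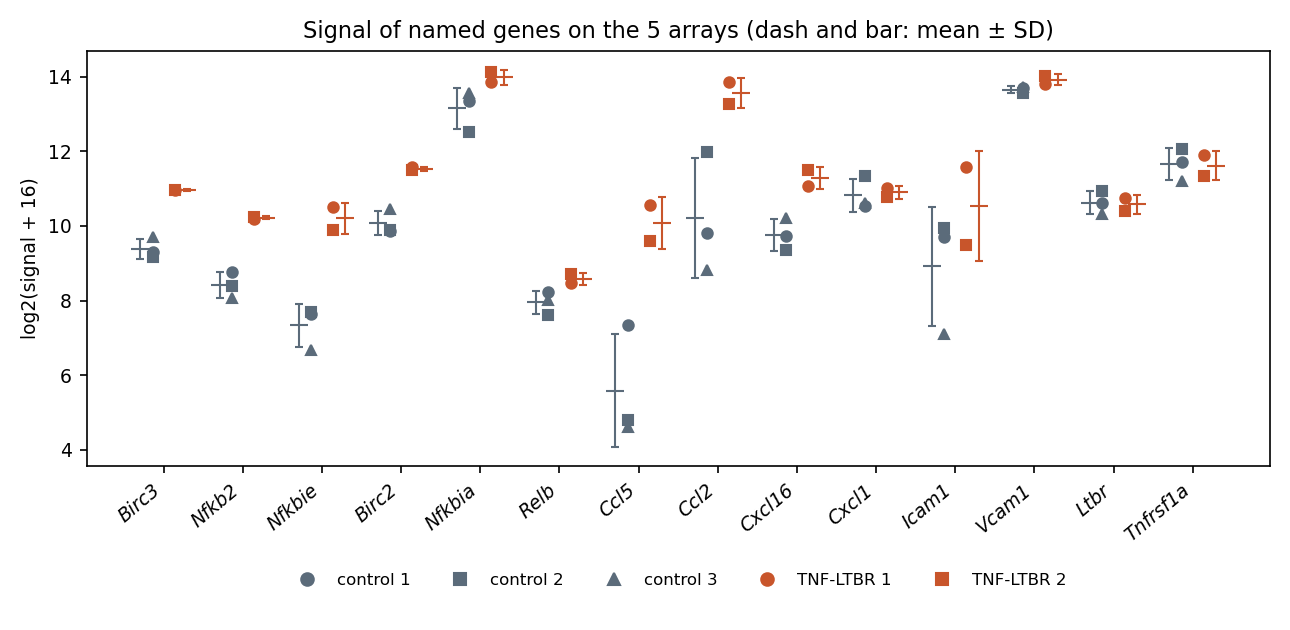
Signal of 14 genes, log2(intensity + 16) on the y axis, with 1 symbol per array and a dash and bar for the mean ± SD of each group. TNF-LTBR arrays lay above all 3 controls for the NF-kB genes Birc3 (2.99-fold), Nfkb2 (3.52-fold) and Nfkbia (1.79-fold) and for the chemokines Ccl5 (4.49 on the log2 scale) and Ccl2 (3.36), while Cxcl1, Icam1, Ltbr and Tnfrsf1a overlapped.

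Inflammatory chemokines, which draw leukocytes to tissue, also rose as a list by camera (adjusted p 1.29e-06), with all 12 measured members higher and a mean difference of 1.49. The list missed the threshold with an estimated correlation (adjusted p = 0.206) and by fry (0.425). Ccl5 lay at 5.58 ± 1.52 in control and 10.07 ± 0.69 in TNF-LTBR, a difference of 4.49 on this scale. Its size depends on the pseudocount, since control arrays 2 and 3 lay at 4.80 and 4.62, where the added 16 exceeds the intensity. It was 3.43 with pseudocount 64 and 5.36 without control replicate 1. Ccl2, which attracts monocytes, lay at 10.20 ± 1.61 and 13.56 ± 0.41, a difference of 3.36 that was 4.24 without control replicate 2 and 2.67 without control replicate 3. Cxcl16 was at 2.87-fold, with 9.77 ± 0.43 in control and 11.29 ± 0.30 in TNF-LTBR. Cxcl1 was nearly level on its brightest probe set, at 1.05-fold, and its direction turned without control replicate 1 (-0.07), control replicate 3 (-0.03) or TNF-LTBR replicate 1 (-0.05). Its other probe sets differed by 0.52 and 0.74 on the log2 scale. Adjusted over the list alone, 2 members passed in limma, Cxcl16 and Ccl5, both at 0.0240. Both TNF-LTBR arrays lay above all controls for 5 members, but the list mean overlapped: it was 8.76, 10.04 and 8.17 on control arrays 1 to 3 and 11.08 and 9.88 on TNF-LTBR arrays 1 and 2. Without TNF-LTBR replicate 1 the mean difference was 0.74, with the list still past camera (adjusted p 0.000436, range over the alternatives 1.21e-09 to 0.00159).

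The apoptosis and survival list passed camera (adjusted p 0.0407) with a mean of 0.31 over 15 members, 9 higher and 6 lower, and a median of 0.04. It missed the threshold with an estimated correlation (adjusted p = 0.525) and by fry for one direction (0.425), and passed fry for either direction (0.0203). Its leading members were again Birc3 and Birc2, which encode inhibitors of apoptosis and are also on the NF-kB list. Birc2 was at 2.75-fold, 10.07 ± 0.32 in control and 11.53 ± 0.06 in TNF-LTBR. Casp8, which encodes the initiator caspase of death receptors and was chosen after its values were seen, was at 1.46-fold. These 3 genes passed when adjusted over the list alone (limma, adjusted p 0.00611, 0.00682 and 0.0499). The camera call was lost in the fits without control replicate 2 (adjusted p 0.0650, mean 0.32), control replicate 3 (0.190, mean 0.24) and TNF-LTBR replicate 1 (0.430, mean 0.17), and its adjusted p over the alternatives ranged from 0.00860 to 0.430.

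Genes of MHC class I antigen presentation rose as a list by camera (adjusted p 1.64e-05), with 13 of 14 members higher and a mean difference of 0.57. The list missed the threshold with an estimated correlation (adjusted p = 0.562) and by fry (0.832), and its array means overlapped, at 11.06, 10.62 and 11.21 in control and 11.19 and 11.89 in TNF-LTBR. Psmb8 and Psmb10, which encode inducible subunits of the immunoproteasome, were at 2.83-fold and 2.25-fold. Psmb10 lay at 9.23 ± 0.25 in control and 10.40 ± 0.40 in TNF-LTBR. The interferon-gamma-inducible GTPases and regulators rose as a list by camera (adjusted p 0.0357), by 0.45 on average with 6 of 8 members higher. They missed the threshold with an estimated correlation (adjusted p = 0.665) and by fry (0.923). Irf1, a transcription factor induced by interferon and NF-kB, lay at 10.26 ± 0.08 in control and 10.83 ± 0.11 in TNF-LTBR, 1.48-fold, and Gbp2, an interferon-induced GTPase, was at 1.91-fold with overlapping groups. The estimated inter-gene correlation was 0.82 for the GTPases and 0.45 for MHC class I, against the preset 0.01. Groupings that mix the titles also passed camera. With control array 3 and TNF-LTBR array 2 against the rest, the adjusted p was 0.00158 for the GTPases and 0.0330 for MHC class I. Without shared-sequence probe sets, a setting that also left out Irf1, the GTPase call was lost (camera adjusted p 0.345, mean 0.40). No member of either list passed in limma when adjusted over the list alone. Without TNF-LTBR replicate 2 the MHC class I mean was 0.22 (camera adjusted p 0.373) and the GTPase mean was -0.12 (0.889), and without control replicate 2 the GTPase mean was 0.05 (0.562). Without TNF-LTBR replicate 1 the means were 0.96 and 1.06, and without control replicate 3 the GTPase mean was 0.72. Over the alternatives the adjusted p ranged from 3.50e-11 to 0.373 for MHC class I and from 9.38e-05 to 0.889 for the GTPases.

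The type I interferon list did not pass (camera adjusted p 0.370), with 12 of 15 members higher and a mean difference of 0.25. Ddx58, a sensor of viral RNA, was at 1.59-fold. This list separated arrays within each group: its mean was 9.89, 8.77 and 10.63 on control arrays 1 to 3 and 9.14 and 10.88 on TNF-LTBR arrays 1 and 2. The mean difference was -0.62 without TNF-LTBR replicate 2 and 1.12 without TNF-LTBR replicate 1. The list passed camera upwards without TNF-LTBR replicate 1 (adjusted p 3.08e-06) and without control replicate 3 (0.0239, mean 0.68), and downwards without TNF-LTBR replicate 2 (0.0177), in a range of 3.08e-06 to 0.654 over the alternatives. It also passed upwards with the replicate number as a block (0.0186, mean 0.68) and with the residual component as a covariate (0.0152, mean 0.25). Control replicate 3 has no partner of its number, so the block takes it out of the comparison. The block is therefore no separate support beside the fit without control replicate 3. The GTPase list followed the same order of arrays, with means of 9.73, 8.92 and 10.50 in control and 9.56 and 10.78 in TNF-LTBR.

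The other 4 of the 9 lists past camera were complement and acute phase (adjusted p 0.0135), cell cycle (0.000276), cholesterol synthesis (0.00731), and cytokines and colony-stimulating factors (0.0481). They missed the threshold with an estimated correlation, at adjusted p of 0.562, 0.562, 0.665 and 0.525, and by fry, at 0.923, 0.913, 0.923 and 0.722. Complement and acute phase genes were 0.87 higher on average, with 12 of 13 members higher. Saa3, an acute phase protein, was at 9.05-fold, but its TNF-LTBR values were 13.40 and 8.63 and overlapped the controls. Its log2 change was 2.54 without control replicate 1, 4.15 without control replicate 2, 0.79 without TNF-LTBR replicate 1 and 5.56 without TNF-LTBR replicate 2. Serping1, which encodes an inhibitor of complement, was at -0.25 on the log2 scale. All 17 cell cycle genes were higher, by 0.41 on average, with Mcm3, a subunit of the replicative helicase, at 1.39-fold and Pcna, the sliding clamp of DNA replication, at 1.18-fold. All 12 cholesterol synthesis genes were higher, by 0.31 on average, with Lss at 0.48 on the log2 scale and Fdps at 1.64-fold, both enzymes of the pathway. The other probe sets of Lss differed by 0.04 and 0.22 on the log2 scale. The groups overlapped for Fdps, whose log2 change was 0.28 without TNF-LTBR replicate 1 and 1.15 without TNF-LTBR replicate 2. Cytokines were 0.36 higher on average, 10 of 13 members, with Il1b at 1.43-fold and Tslp at 2.32-fold. The groups overlapped for Tslp, whose log2 change was 0.64 without TNF-LTBR replicate 2 and 1.79 without TNF-LTBR replicate 1.

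No member of these 4 lists passed in limma when adjusted over its list alone, and the array means of the groups overlapped in each of the 4. Cell cycle and cholesterol lists also passed camera upwards with control array 1 and TNF-LTBR array 1 against the rest (adjusted p 0.000412 each). Complement did so with control array 2 and TNF-LTBR array 1 (0.00312). Cytokines passed in no grouping of 1 control with 1 TNF-LTBR array. Without TNF-LTBR replicate 1 the means were 0.16 for complement (camera adjusted p 0.278), -0.04 for cell cycle (0.894) and -0.10 for cholesterol synthesis (0.646). Without control replicate 3 they were 0.42 (0.190), 0.13 (0.126) and 0.11 (0.252). Without TNF-LTBR replicate 2 they were 1.57, 0.89 and 0.72, and without control replicate 2 the complement mean was 1.41. The cytokine call was lost in each fit that left out 1 array, with adjusted p of 0.0620 to 0.190, a mean of 0.21 without control replicate 1 and of 0.55 without TNF-LTBR replicate 2. Over the alternatives the adjusted p ranged from 1.86e-05 to 0.289 for complement, 8.58e-10 to 0.894 for cell cycle, 4.97e-06 to 0.646 for cholesterol and 0.0200 to 0.899 for cytokines.

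**Figure D2:**
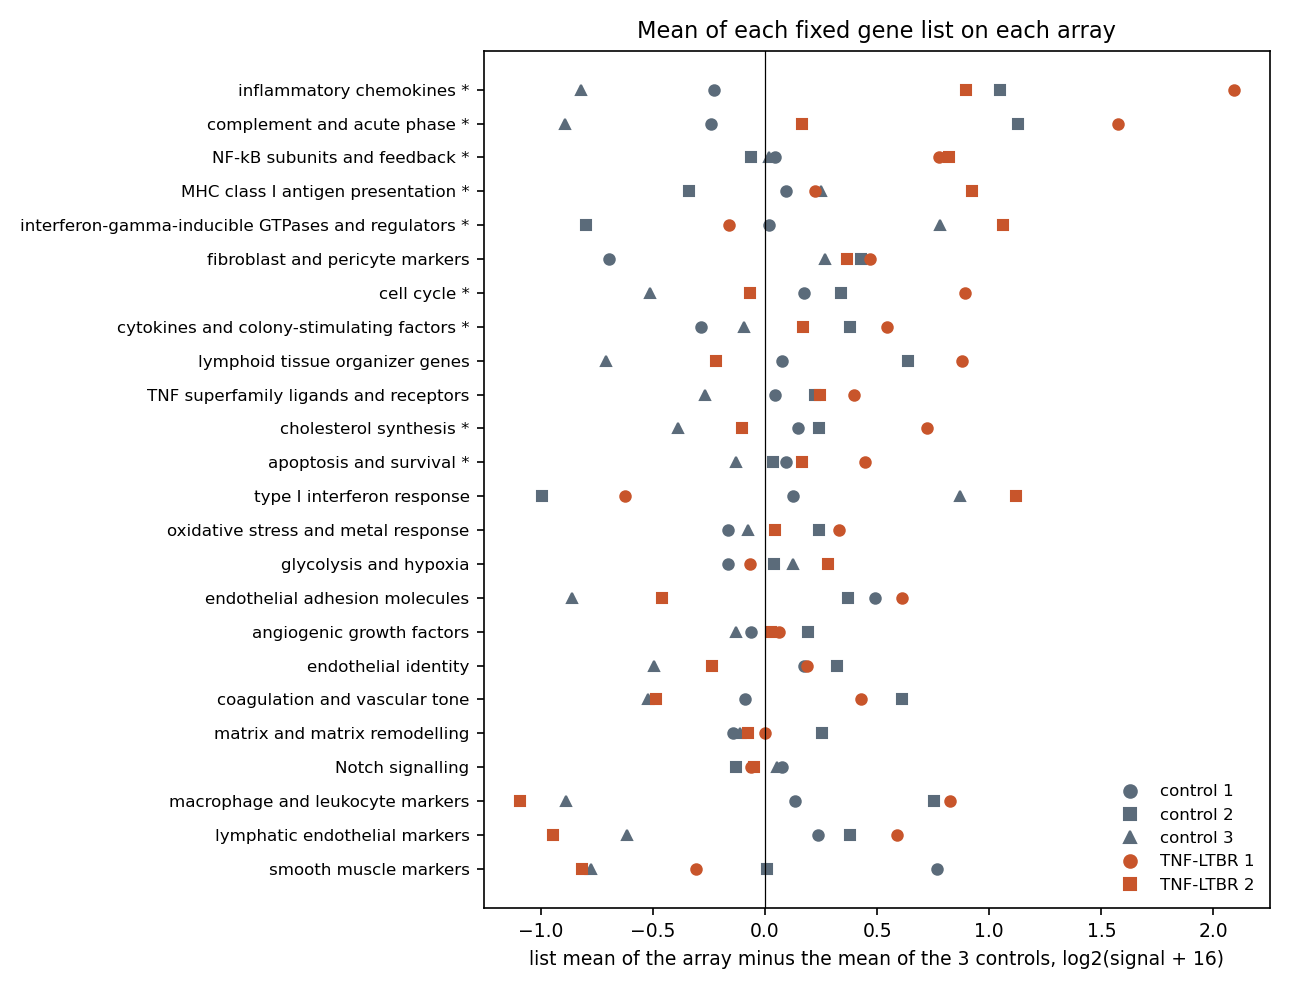
Mean of each of the 24 tested gene lists on each array minus the mean of the 3 control arrays, in log2(intensity + 16) on the x axis, with 1 symbol per array; asterisks mark lists past camera at the preset correlation. Both TNF-LTBR arrays lie above all controls for 3 of the 24 lists, against 10% by chance, so this count is near chance. Of these 3, NF-kB has the closest values within each group (SD 0.06 in control and 0.03 in TNF-LTBR).

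Transcripts of the receptors themselves were level between the groups. Tnfrsf1a lay at 11.67 ± 0.43 in control and 11.61 ± 0.39 in TNF-LTBR, and Ltbr at 10.62 ± 0.30 and 10.58 ± 0.25. Both differences, -0.05 and -0.04, were smaller than the SD of either group, and both were positive without TNF-LTBR replicate 2 (0.22 and 0.14) and without control replicate 2 (0.15 and 0.12). The list of TNF superfamily ligands and receptors did not pass (camera adjusted p 0.198, mean 0.32, 5 of 9 members higher). It passed with every probe set on its own (mean 0.31, adjusted p 0.0393, range over the alternatives 0.0393 to 0.478), and the mean was 0.19 without control replicate 3. Within it, Tnfrsf9, a costimulatory receptor, lay at 8.86 ± 0.54 in control and 10.78 ± 0.15 in TNF-LTBR, 3.81-fold, and was the 1 member to pass when adjusted over the list alone (limma, adjusted p 0.0170).

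Genes of lymphoid tissue organizers, a cell state that the series title names for smooth muscle cells, did not pass as a list (camera adjusted p 0.454, mean 0.33, 5 of 7 members higher). They passed with every probe set on its own (mean 0.31, adjusted p 0.0223, range over the alternatives 0.0223 to 0.988). Cxcl13, the chemokine that attracts B cells, was at 0.858-fold, with 7.81 ± 0.22 in control and 7.59 ± 0.16 in TNF-LTBR. Il7, a lymphocyte survival factor, was level at 7.42 ± 0.28 and 7.42 ± 0.04, its direction turned with quantile normalization, median centring and other alternatives, and its dimmer probe set differed by -0.23. The leukocyte adhesion molecule Vcam1 was at 1.20-fold on its brightest probe set, 13.65 ± 0.09 in control and 13.92 ± 0.15 in TNF-LTBR, and its other probe sets differed by 0.69 and 0.77. Icam1 was at 3.08-fold, but with values of 9.70, 9.95 and 7.09 in control and 11.58 and 9.50 in TNF-LTBR the groups overlapped. Its log2 change was 0.71 without control replicate 3, 0.58 without TNF-LTBR replicate 1 and 2.66 without TNF-LTBR replicate 2. Madcam1, Sele and Tnfsf13b were below the brightness filter, and in the fit without a filter each had a limma adjusted p of 1.000. The adhesion list did not pass (mean 0.07, camera adjusted p 0.643). Its mean was -0.38 without control replicate 3, -0.46 without TNF-LTBR replicate 1 and 0.65 without TNF-LTBR replicate 2, and -0.35 with the replicate number as a block (adjusted p 0.0810, range over the alternatives 0.0810 to 0.900). The mean of the organizer list was -0.02 without control replicate 3, -0.22 without TNF-LTBR replicate 1 and 0.88 without TNF-LTBR replicate 2.

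The other lists did not pass camera. The 7 endothelial identity genes past the brightness filter differed by -0.03 on average (adjusted p 0.993), with Plvap at 1.35-fold, lymphatic markers by -0.18 (0.370), with Sema3d at -1.56 on the log2 scale, and coagulation and vascular tone by -0.03 (0.993). Matrix genes differed by -0.04 (0.379), oxidative stress genes by 0.19 (0.267), with the metallothionein Mt2 at 1.94-fold, and glycolysis and hypoxia genes by 0.10 (0.129). Notch genes differed by -0.05 (0.454), with the target gene Hes1 at -0.66 on the log2 scale, and angiogenic growth factors by 0.04 (0.993), with Apln at 1.54-fold and Vegfc at 3.26-fold. Among markers of other cells, smooth muscle genes differed by -0.56 (0.231), with Tpm2 at -0.27 and Synpo2 at 0.33, fibroblast and pericyte genes by 0.41 (0.198), with Rgs5 at 2.28 and Pdgfra at 0.93, and macrophage genes by -0.13 (0.970), with Cd53 at 0.57. Without a brightness filter the endothelial identity list was at -0.27 (adjusted p 0.0548, range over the alternatives 0.0548 to 0.998). Without control replicate 3 and without TNF-LTBR replicate 1 its mean was -0.27 and -0.24 and that of coagulation -0.29 and -0.49, and without TNF-LTBR replicate 2 they were 0.25 and 0.43. With the replicate number as a block they were -0.27 (0.128) and -0.29 (0.0502, range 0.0502 to 0.998). The groups overlapped for Mt2, Vegfc and Rgs5. On the log2 scale Vegfc was at 2.37 and Rgs5 at 3.33 without control replicate 2, Mt2 at 0.31 without TNF-LTBR replicate 1 and 1.60 without TNF-LTBR replicate 2, and Sema3d at -0.97 and Pdgfra at 0.45 without control replicate 1. Cd53 was at 0.27 without TNF-LTBR replicate 1, 0.88 without control replicate 2 and 0.87 without TNF-LTBR replicate 2, Synpo2 at 0.12 without control replicate 3, and Tpm2 at -0.17 without control replicate 1. Plvap was at 0.0998 without TNF-LTBR replicate 2 and 0.77 without TNF-LTBR replicate 1. Without TNF-LTBR replicate 1 the lymphatic (-0.94, adjusted p 0.00406) and glycolysis lists (0.28, 0.00105) passed, and so did the macrophage list, downwards (-1.09, 0.00424). Without TNF-LTBR replicate 2 the macrophage list passed upwards (0.83, 0.00636). Without control replicate 1 the matrix list passed (-0.11, 0.0495), and without control replicate 3 the smooth muscle (-0.95, 0.0239) and fibroblast lists (0.55, 0.0239) did. With the replicate number as a block, which also takes control replicate 3 out of the comparison, the smooth muscle (-0.95, 0.00548) and fibroblast lists (0.55, 0.00235) passed. With every probe set on its own the oxidative stress (0.23, 0.00850) and fibroblast lists (0.67, 0.00447) passed, and with the stricter filter the glycolysis (0.10, 0.0450) and smooth muscle lists (-0.84, 0.0194). Over the alternatives the adjusted p was at most 0.891 for lymphatic, 0.559 for glycolysis, 0.998 for macrophage, 0.985 for matrix, 0.874 for smooth muscle, 0.848 for fibroblast and 0.818 for oxidative stress genes, and at least 0.00406, 0.00105, 0.00424, 0.0495, 0.00548, 0.00235 and 0.00850. MHC class II and lymphocyte lists kept 4 and 2 genes, too few to test, with mean differences of -0.12 and 0.57. Camera's direction was opposite to the mean for endothelial identity, coagulation, macrophage and angiogenic genes, and mean and median differed in sign for coagulation, angiogenic and MHC class II genes.

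Across all 10916 genes, limma called 0 higher and 0 lower. This count holds with the arrays unpaired or paired by number. With pairs read from the array correlations, not the labels, limma called 97 genes higher and 91 lower, in a fit with 1 residual degree of freedom whose pairs were chosen on the same values. At an unadjusted p under 0.05 there were 192 genes, 105 higher and 87 lower, against 545.8 by chance, and 113 without control replicate 1. Both TNF-LTBR arrays lay above all controls for 758 genes, 6.94%, and below for 692, 6.34%, against 10% by chance in each direction. Of these, 34 were at least 2-fold higher and 22 at least 2-fold lower. The smallest unadjusted p belonged to Spib, which encodes an Ets family transcription factor, at 6.71 ± 0.27 in control and 9.30 ± 0.23 in TNF-LTBR, 5.99-fold. Dclk1, a microtubule-associated kinase, followed at 3.38-fold, and among genes lower in TNF-LTBR the smallest p belonged to the laminin receptor subunit Itga7, at -0.82 on the log2 scale. These 3 genes were chosen after their values were seen, and their limma adjusted p was 0.999.

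The arrays did not cluster by group. Over the tested genes, control array 2 and TNF-LTBR array 1 had a Pearson correlation of 0.976, and control array 3 and TNF-LTBR array 2 had 0.978. These are correlations across genes, which are not independent replicates. Control arrays correlated with each other at 0.895 to 0.946, and the TNF-LTBR arrays at 0.901. The first principal component held 65.9% of the variance and ran from TNF-LTBR array 1 and control array 2 to TNF-LTBR array 2 and control array 3. Macrophage markers went with it, with list means of 8.96, 9.58 and 7.94 on control arrays 1 to 3 and 9.65 and 7.73 on TNF-LTBR arrays 1 and 2. The second component, with 19.4%, set control array 1, at 35.31, apart from the other arrays, at -14.58 to -4.03. The third component, with 9.97%, held control arrays 2 and 3 at -17.03 and -14.03 and the TNF-LTBR arrays at 11.44 and 13.93, with control array 1 at 5.69.

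**Figure D3:**
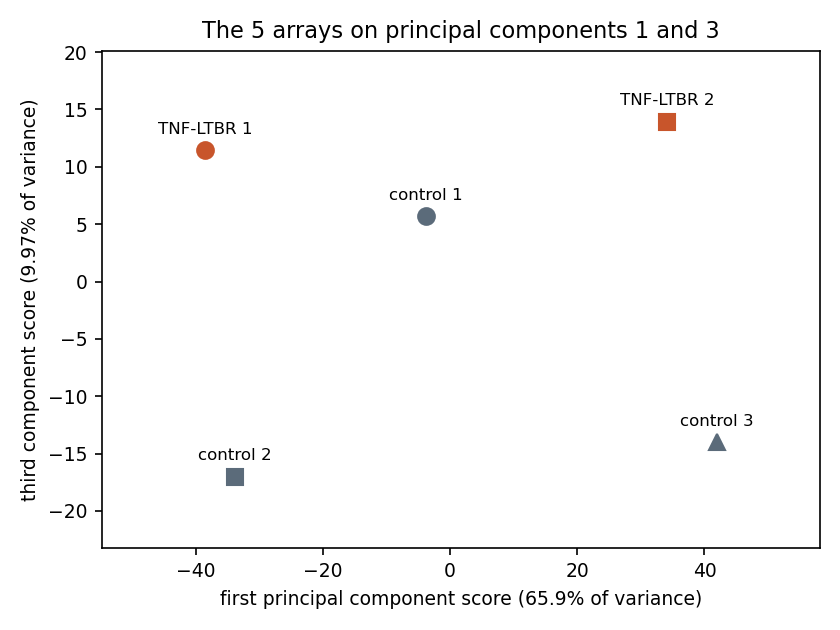
Scores of the 5 arrays on the first (x axis, 65.9% of variance) and the third (y axis, 9.97%) principal components of the tested genes, in units of log2(intensity + 16), with 1 point per array. Each TNF-LTBR array lies near 1 control array along the first component, -38.53 beside -33.84 and 34.14 beside 42.02.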

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

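The principal component of the residuals as a covariate and the pairing of arrays by their correlation were chosen after seeing the data, and all other alternatives before. In 17 alternatives of the gene fit, all but that pairing, limma again called 0 genes higher and 0 lower, with a smallest adjusted p between 0.182 (residual component, 798 genes at an unadjusted p under 0.05) and 1.000. Leaving out one TNF-LTBR array leaves 1, which is then assumed to vary like the controls. The 9 lists past camera became 4 without shared-sequence probe sets, 0 with an estimated correlation and 1 (NF-kB) by fry. Of these 9, 8 were kept without control replicate 1, 6 without control replicate 2 or TNF-LTBR replicate 2, and 4 without control replicate 3 or TNF-LTBR replicate 1, where 3 and 4 other lists were called instead. The cause was not tested. NF-kB and inflammatory chemokines passed in all 17 alternatives at the preset correlation, with means of 0.53 to 0.82 and 0.74 to 2.07 (the pairing by correlation is not among these 17). MHC class I passed in 16, cell cycle and interferon-gamma-inducible GTPases in 14, complement in 13, cholesterol synthesis in 12, apoptosis in 9 and cytokines in 3. Leaving out the eBayes trend does not alter camera. Each of these counts, the 17 included, therefore holds 1 repeat of the main result. Of 46 named and tested genes, 42 kept their direction in every fit that kept them, 13 to 17 fits per gene without the pairing by correlation, and Il7, Cxcl1, Ltbr and Tnfrsf1a did not. The widest ranges of log2 change among them, over the fits that kept each gene, were 0.79 to 5.56 for Saa3, 0.58 to 2.66 for Icam1 and 3.43 to 5.36 for Ccl5.

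Samples of the groups share only their numbers. Deviations from the group means correlated at 0.127 for number 1 and -0.799 for number 2. Across numbers, they correlated at 0.799 for control array 2 with TNF-LTBR array 1 and 0.814 for control array 3 with TNF-LTBR array 2. The deviations of the 2 TNF-LTBR arrays are mirror images of each other (correlation -1). The 0.799 is therefore the value of number 2 with its sign turned, and the values by number and across numbers are not separate evidence on pairing. A block of control array 2 with TNF-LTBR array 1 and control array 3 with TNF-LTBR array 2 called 97 genes higher, 91 lower and 10 lists. The pairs were read from the same values, 5 other pairings of the groups called 0 genes, and the fit leaves 1 residual degree of freedom, so these calls are no independent evidence. Of 8 other splits paired by the same rule, 0 called as many as these 188 genes, and the highest called 62. The split of control arrays 2 and 3 from the rest is not among the 8. It holds the same pairs and called the same number, 188, with directions swapped. With pairs not chosen by correlation, mixed splits called more. Control array 2 and TNF-LTBR array 1, paired with control array 3 and TNF-LTBR array 2, called 3707. With a replicate block, 0 genes higher, 0 genes lower and 7 lists were called. Control replicate 3 has no partner of its number, so this block takes it out of the comparison. Complement, cytokine, apoptosis, cell cycle and cholesterol lists were then not called, and type I interferon, smooth muscle and fibroblast lists were. With this block Cxcl1 was at -0.0324, Il7 at -0.148, and the lists of lymphoid tissue organizer genes at -0.0243, adhesion molecules at -0.35, endothelial identity at -0.27, coagulation at -0.29 and macrophage markers at -0.58.

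The cause of the other reversed directions was not tested. Il7 was at -0.00143 with pseudocount 64, -0.0166 with quantile normalization, -0.0241 with median centring and -0.0859 with array weights. A list's direction here is that of camera or fry, which can differ from the sign of its mean. Without a filter, adhesion molecules turned at -0.0238, endothelial identity at -0.27, coagulation at -0.0215 and macrophage markers at -0.16. With the stricter filter, cytokines turned at 0.0664 (adjusted p 0.899, range 0.0200 to 0.899) and angiogenic factors at 0.0529. Angiogenic factors also turned with quantile normalization (0.0499) and median centring (0.0182). With every probe set on its own, endothelial identity turned at -0.16 and macrophage markers at -0.26, and the latter at -0.26 without shared-sequence probe sets. With array weights, adhesion molecules turned at -0.15, endothelial identity at -0.14, coagulation at -0.12 and macrophage markers at -0.33. Coagulation turned at -0.0299 by fry. With the residual component, endothelial identity turned at -0.0260, coagulation at -0.0299 and macrophage markers at -0.13.

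Leaving out each array in turn gave log2 changes of -0.0738 to 0.33 for Cxcl1, -0.15 to 0.13 for Il7, -0.22 to 0.14 for Ltbr and -0.33 to 0.22 for Tnfrsf1a. List means ranged from -0.22 to 0.88 for lymphoid tissue organizer genes, -0.46 to 0.65 for adhesion molecules, -0.27 to 0.25 for endothelial identity, -0.94 to 0.59 for lymphatic markers and -0.62 to 1.12 for type I interferon genes. They ranged from -0.12 to 1.06 for interferon-gamma-inducible GTPases, -0.49 to 0.43 for coagulation, -0.11 to 0.0903 for matrix genes, -0.10 to 0.72 for cholesterol synthesis and -0.0686 to 0.28 for glycolysis and hypoxia. The remaining ranges were -0.12 to -0.0168 for Notch genes, -0.10 to 0.14 for angiogenic factors, -0.95 to -0.18 for smooth muscle markers and -1.09 to 0.83 for macrophage markers.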

Other observations

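The tests below were chosen after the results were seen, except the count of gene lists over the splits of the arrays. Genes named here outside the rule were chosen after their values were seen. Along the first principal component, interferon and MHC class I genes lay towards control array 3 and TNF-LTBR array 2. All 8 interferon-gamma-inducible GTPases and regulators, 14 of 15 type I interferon genes and 11 of 14 MHC class I genes loaded in that direction. The other way loaded all 9 macrophage markers, 10 of 13 complement genes, 8 of 12 chemokines, 14 of 17 cell cycle genes and 3 of 4 MHC class II genes. Lyz2, a lysozyme of myeloid cells, was at 10.11, 11.74 and 7.66 on the control arrays and 11.95 and 6.37 on the TNF-LTBR arrays. Ccl11, the eosinophil attractant, had the most negative loading, with 7.87, 12.95 and 4.22 in control and 12.95 and 4.43 in TNF-LTBR. Fibroblast and pericyte markers were split, 7 towards control array 3 and 5 the other way. Lum was at 10.18, 9.70 and 13.66 in control and 10.13 and 13.66 in TNF-LTBR, and Thy1 at 11.34, 13.58 and 7.41 and at 13.12 and 7.17. Smooth muscle markers were split 3 and 5.

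Of the 20 endothelial identity genes, 7 passed the brightness filter, against 12 of 12 fibroblast and pericyte markers, 8 of 12 smooth muscle markers and 9 of 16 macrophage markers. Pecam1 was at 7.75, 7.47 and 6.17 on control arrays 1 to 3 and 7.10 and 6.10 on TNF-LTBR arrays 1 and 2, and Cdh5 was at 7.97, 7.12 and 6.16 and at 7.24 and 5.48. Vwf was at 4.54, 4.53 and 4.19 in control and 4.45 and 4.24 in TNF-LTBR, where the added 16 exceeds the intensity. The brightest of the 20, Eng, was at 10.613, 10.872 and 10.835 and at 10.624 and 10.739. The fibroblast and pericyte marker Pdgfra was at 11.05, 12.52 and 12.47 and at 13.14 and 12.75. Probe sets differ in brightness for reasons other than transcript abundance, so these counts and levels do not rank the cell types. That the cells are endothelial rests on their labels and was not tested. These values give the label no support, since most endothelial identity genes fell below the filter and all fibroblast and pericyte markers passed it.

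The NF-kB list was 0.80 higher in TNF-LTBR. Control arrays 2 and 3, at opposite ends of the first component, differed in the list mean by 0.0804, which argues against the differences between cultures along that component as the whole source of the shift. The 10 splits of the 5 arrays into 3 and 2 are too few for a share under 0.05. The real split, 1 of 10, gave a mean difference of 0.80 and the highest other 0.571 in size. The stimulation that the titles name stays among the open explanations, as untested, beside any other difference between these cultures that follows the groups.

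Control array 2 resembled TNF-LTBR array 1, and control array 3 TNF-LTBR array 2, more than arrays of their own group. Whether an array was mislabelled could not be settled. In the NF-kB list mean the lowest TNF-LTBR array exceeded the highest control by 0.732, against an SD of 0.06 between controls. This list was taken after it was seen to separate the titles. It bears on labels only if it marks the stimulation, which was not tested. Other cell types in the cultures are a candidate explanation, since 3 of 5 marker lists (macrophage, fibroblast and pericyte, and lymphatic, the last with 2 genes also on another list) had median loadings outside the central 95% of 10000 random lists matched on level. That test is weak, because 15 of all 26 lists lay outside, and the members of the fibroblast and lymphatic lists loaded both ways. RNA quality could not be settled from the control probe sets: Actb ratios of 3' to 5' signal differed by up to 0.105 within the similar pairs and by as little as 0.0079 across them, and Gapdh ratios by 0.0115 and 0.0177. Over all 5 arrays the Actb ratio lay between 1.33 and 1.44 and the Gapdh ratio between 0.749 and 0.782.

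Of the 10 splits of the arrays into 3 and 2, 3 called at least the 9 lists of the real one, itself included, and the highest other called 10. The split of control array 3 and TNF-LTBR array 2 from the rest called 758 genes and that of control array 2 and TNF-LTBR array 1 called 159, which points to a structure of the samples other than the groups. The 10 splits are too few for a share under 0.05.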
